A study of Homo sapiens with 8 samples.

How the data were processed

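RNA of 8 samples of TeloHAEC, a telomerase-immortalised human aortic endothelial cell line, was sequenced as 4 control and 4 estradiol libraries, all grown with palmitic acid in the medium. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates were separate cultures or experiments, so the p-values measure only the spread between these libraries, which may be technical. The doses of estradiol and palmitic acid and the time of exposure are not given in the sources used here.

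The authors deposited a single table of FPKM values (fragments per kilobase of transcript, scaled to a total of fragments for each library), with a row per gene symbol and a column per library. Per the submitters' processing notes, fastp version 0.20.1 and HTSeq (version not named) were used; the aligner, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. No coordinates are printed for that reason, and levels of antisense genes are uncertain. The table held 34415 genes, of which 23471 were above 0 in at least 1 library. All 8 sample columns were used.

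FPKM values of a gene are whole multiples of what 1 read is worth, so reads were recovered from the steps between the values of each gene. All 152348 values above 0 (100.0%) came out as whole reads: rebuilt from whole reads and lengths, each matched the deposited value within a relative tolerance of 1e-06, with a largest deviation of 2.22e-16. For 98.76% of genes the first step gave a gene length within 0.01 of a whole number, as 2% of random lengths would be, and for 290 genes the reads were multiplied by a small whole number to give one. On simulated values for 22551 genes of the estradiol and control libraries, 98.98% of genes were recovered exactly before the length step and 100.0% up to a common whole factor. The recovered depth ranged from 33421051 to 39899258 reads per library. Between 99.972% and 99.974% of the reads in the authors' denominators lay in the rows used, and the rest were not analysed here. The scaling total was thus almost wholly reads assigned to genes of the table, and the recovered depth counts only such reads.

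Gene tests used limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(FPKM + 1), two-sided, for the 10720 genes with a mean FPKM of at least 1 over the 8 libraries. Fold changes are on that scale, which understates the change of low genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted, with no fold threshold and no block. Since the unit is FPKM, no count model was the main test. Before the data were examined, 29 gene lists were fixed, and the 26 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over lists. Library composition and genes under the filter were compared with exact two-sided permutation tests over the 70 relabellings of the 8 libraries, whose smallest p is 0.0286. GC content came from reference transcripts matched by gene name, for 98.2% of the tested genes. It was used only as a gene property. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.

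The rule for named genes was also fixed before the data were examined. It takes up to 10 genes in each direction past the threshold with groups that do not overlap, up to 4 members of each list past the threshold or else the 2 with the smallest p, given as values, 14 genes named in advance (3 estrogen receptors and 11 endothelial or mesenchymal genes), and, where fewer than 5 genes passed in a direction, the 5 with the smallest unadjusted p. It named 73 genes.

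The gene test was tested on simulated data for the estradiol against control comparison with 10720 genes, of which 50 were changed at each fold. The changed genes were drawn from genes of intermediate level, so the shares do not cover the lowest and highest genes. With the residuals of the real libraries, 0% of genes changed 1.25-fold, 14% of those changed 1.5-fold, 90% of those changed 2-fold and 100% of those changed 3-fold were recovered, with 0 false calls. Those residuals were centred within each group, so unchanged genes had no group difference. The 0 false calls were thus fixed in advance, and the shares leave out the error of an estimated change. With independent noise the shares were 8%, 56%, 70% and 100%, with 10 false calls. Of 100 unchanged random lists of 16 genes, drawn from independent noise, camera gave an unadjusted p under 0.05 for 4. Genes do not vary together in such noise, so this does not test the preset correlation on the real lists.

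Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, a filter at a mean FPKM of 5, rescaling to a common total, median-of-ratios size factors, quantile normalization, no mean-variance trend, array weights, the replicate number as a block, each library left out in turn, a 2-fold threshold, an exact permutation test per gene, camera with an estimated correlation, and fry. Chosen after seeing the data were limma-voom on the recovered reads, removal of the GC trend of each library by a spline with 5 degrees of freedom, a batch term for control replicate 3 and estradiol replicate 4, fits without these libraries and also without estradiol replicate 2, an exact permutation test of each list mean, and shares of recovered reads. No library pair of a group agreed within counting noise. The chi-square per degree of freedom was at least 6.94 over genes with at least 20 recovered reads in the pair. No library was therefore treated as a repeat run of another, and each was counted as a replicate. Technical differences between libraries also raise this value, so it does not show that the replicates were independent.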

Results

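The series asked what estradiol, the main estrogen, does in human aortic endothelial cells kept in medium with palmitic acid, a saturated fatty acid supplied to mimic an atherosclerosis-prone setting. Transcript levels were given as FPKM for 4 control and 4 estradiol libraries of the TeloHAEC line. The recovered depth was 33421051 reads in the shallowest library, estradiol replicate 2, and 39899258 reads in the deepest, control replicate 4. Between 10609 and 10959 genes reached 1 FPKM in a library.

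Transcripts of the nuclear estrogen receptors were close to the detection limit in both groups. ESR1, which encodes estrogen receptor alpha, measured 0.00485 ± 0.00628 FPKM in control and 0.00851 ± 0.0144 in estradiol libraries (SD, n = 4 each; exact permutation p = 0.83), from 0 to 19 recovered reads per library. ESR2, which encodes estrogen receptor beta, measured 0.00978 ± 0.00681 and 0.012 ± 0.00385 FPKM (SD, n = 4 each; exact permutation p = 0.629), from 0 to 7 reads. GPER1, a membrane receptor for estrogens, measured 0.216 ± 0.110 and 0.202 ± 0.0447 FPKM (SD, n = 4 each; exact permutation p = 0.943), from 13 to 41 reads. A difference in these receptors was not detectable at this depth. The list of 17 estrogen-induced genes that could be tested, mostly known from breast cells, did not pass (mean log2 fold change -0.04, camera adjusted p = 0.0631). It passed as lower under 7 of 25 alternatives (adjusted p from 0.0235 to 0.976 over the 25). These were rescaling to a common total (0.0335), median-of-ratios size factors (0.0324), a filter at 5 FPKM (0.0235), GC removal (0.0429) and the fits without control replicate 3 or estradiol replicate 1 or 3. Without estradiol replicate 4 its mean was 0.0090, and with an estimated correlation the adjusted p was 0.530. Its members with the smallest p were CCND1, a G1 cyclin, at 93.5 ± 6.15 and 86.8 ± 2.93 FPKM, and STC2, a secreted glycoprotein, at 78.6 ± 5.64 and 73.1 ± 6.27 FPKM (SD, n = 4 each, control first).

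The cells carried endothelial transcripts in both groups. Among the genes chosen in advance, PECAM1, an endothelial adhesion molecule, measured 42.6 ± 2.65 FPKM in control and 42.0 ± 2.79 in estradiol libraries, and CDH5, the endothelial cadherin, 129 ± 19.5 and 125 ± 15.2 (SD, n = 4 each). NOS3, the endothelial nitric oxide synthase, measured 9.19 ± 2.15 and 8.55 ± 1.32 FPKM, and KLF2, a flow-responsive transcription factor, 9.11 ± 3.31 and 7.86 ± 0.825. VWF, von Willebrand factor, was under the filter at 0.309 ± 0.0495 and 0.284 ± 0.0567 FPKM. Of genes tied to mesenchymal or contractile cells, VIM (vimentin) stood at 3948 ± 336 and 3822 ± 105 FPKM, FN1 (fibronectin) at 649.7 ± 67.6 and 647 ± 71.2, ACTA2 (smooth muscle actin) at 12 ± 1.66 and 11.6 ± 1.70 and TAGLN (transgelin) at 7.17 ± 1.27 and 7.35 ± 1.91. SNAI2, a transcription factor of mesenchymal transition, and COL1A1, a collagen chain, were under the filter, at 0.223 ± 0.0503 and 0.196 ± 0.0883 FPKM and at 0.0407 ± 0.0174 and 0.0472 ± 0.0272 FPKM. None of these genes passed the limma test or, under the filter, the exact permutation test. Of the markers of other cell types, 2 of 24 macrophage genes (LAPTM5 and CD68), 3 of 16 epithelial genes (KRT19, KRT7 and CLDN7) and 0 of 14 fibroblast genes reached a mean of 1 FPKM, so these lists were not tested at this filter. Without the filter none of the 3 passed camera (adjusted p = 0.296, 0.395 and 0.770). LAPTM5 and KRT19 were well above that level, with means over all libraries of 49.5 and 48.9 FPKM. The median member stood at 0.00847 FPKM in the macrophage list and 0.0213 in the epithelial list.

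No gene passed the threshold between estradiol and control. Of 10720 genes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.999989. At an unadjusted p under 0.05 there were 26 genes, 12 higher and 14 lower, fewer than the 5% of genes that chance gives on average. The spread between libraries was wide, with a median SE of 0.125. In 2 fits chosen after seeing the data it was smaller. It was 0.0553 (351 genes) with a batch term for control replicate 3 and estradiol replicate 4, and 0.0586 (249 genes) with the GC trend removed. Both counts were also under 5% of the genes tested, so the smaller spread uncovered no excess over chance. The low count of 26 goes with that spread and does not show that estradiol had no effect. limma-voom on the recovered reads, chosen after seeing the data, gave 0 genes and 22 at an unadjusted p under 0.05. In the exact permutation test per gene, 57 genes reached the smallest p of 0.0286, at which chance puts 2.86% of genes, and 0 passed after adjustment. The median half-width of the 95% interval of a log2 fold change was 0.279, which includes that spread between libraries. For 99.4% of genes the interval lay within a 2-fold change of FPKM + 1 in either direction. For low genes this allows a larger change of FPKM itself.

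The genes with the smallest unadjusted p in each direction did not pass either. Among higher values were HIF1A-AS1, an antisense transcript of the HIF1A locus, at 2.75 ± 0.143 FPKM in control and 4.13 ± 0.853 in estradiol libraries (log2 fold change 0.44 ± 0.12 SE), and NCK1-DT, LINC02454, SDCBP2-AS1 and C11orf71, with log2 fold changes of 0.23, 0.23, 0.19 and 0.22. The strand setting of the counting is not given, so the antisense transcripts are uncertain. HIF1A-AS1 and SDCBP2-AS1 were highest in estradiol replicate 2, a library rich in antisense transcripts, at 5.23 and 1.38 FPKM. In the other estradiol libraries they stood at 3.23 to 4.30 and 1.07 to 1.29, against at most 2.92 and 1.09 in control libraries. Among lower values were SDHAF3, an assembly factor of succinate dehydrogenase, at 1.70 ± 0.159 and 1.28 ± 0.156 FPKM (log2 fold change -0.25 ± 0.08 SE), LOC105378179 and LOC644656, with log2 fold changes of -0.50 and -0.23, RPA3, a subunit of a single-strand DNA binding complex, at -0.25, and MX1, an interferon-induced GTPase, at -0.36 (SD and SE over n = 4 per group).

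Heat shock genes were higher as a list with estradiol. This list holds cytosolic chaperones under the transcription factor HSF1. Its 16 tested members had a mean log2 fold change of 0.13, with a positive value in 16 of 16, and the list passed camera (adjusted p = 6.46e-11; adjusted p = 0.00805 with an estimated correlation). Directional fry, which tests the list alone, also gave a call (adjusted p = 0.00278). Mixed fry, which counts changes in either direction, did not (adjusted p = 0.966). DNAJB1, a co-chaperone, measured 127 ± 9.59 FPKM in control and 149 ± 16.2 in estradiol libraries, and HSPA1B, an inducible HSP70 gene whose near-identical copy HSPA1A makes its level uncertain, 284 ± 34.7 and 333 ± 37.6 (SD, n = 4 each). No member passed over all genes or adjusted over the list alone (lowest adjusted p 0.600 by limma). The mean over the list was 7.22 ± 0.0488 in control and 7.35 ± 0.0342 in estradiol libraries (log2 scale, SD, n = 4), with every estradiol library above every control library. The exact permutation p of that mean was 0.0286, the smallest 8 libraries can give, and 0.743 after adjustment over 26 lists, at which no lone list can pass. With the GC trend of each library removed, chosen after seeing the data, the mean log2 fold change was still 0.13, but the groups overlapped, at 7.22 ± 0.0748 and 7.35 ± 0.0615 (SD, n = 4), and the camera adjusted p was 0.0555 with an estimated correlation. In the 6 libraries without control replicate 3 and estradiol replicate 4 it was 0.0678 with an estimated correlation, at a mean log2 fold change of 0.14.

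Mitosis genes had higher values with estradiol, with a call that rested on the preset correlation. The 34 members had a mean log2 fold change of 0.10, with a positive value in 32, and camera gave an adjusted p of 1.80e-13 (adjusted p = 0.0936 with an estimated correlation). CCNB2, a mitotic cyclin, measured 19.5 ± 1.65 and 23.0 ± 1.93 FPKM, and AURKA, a spindle kinase, 17.6 ± 1.23 and 19.5 ± 0.770 (SD, n = 4 each, control first); 0 members passed limma adjusted over the list alone. Without estradiol replicate 4 the mean log2 fold change was 0.049 (camera adjusted p = 0.0367). The 27 DNA replication genes of the S phase list did not pass (mean log2 fold change -0.02, camera adjusted p = 0.353). In this list TYMS stood at 9.47 ± 0.238 and 10.4 ± 0.441 FPKM and CCNE2 at 1.43 ± 0.346 and 1.17 ± 0.278.

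**Figure D1:**
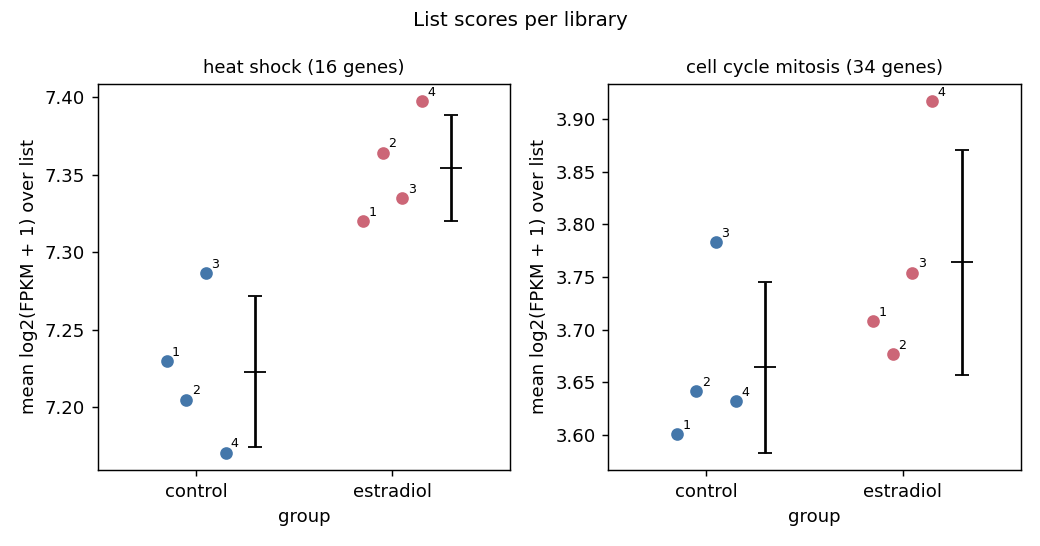
Mean log2(FPKM + 1) over the 16 heat shock genes and the 34 mitosis genes in each library, with points numbered by replicate and bars showing the group mean and SD (n = 4). The estradiol libraries lie above all control libraries for heat shock genes, while control replicate 3 overlaps the estradiol libraries for mitosis genes.

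Of the 8 lists that passed camera with the preset correlation, 6 were lower with estradiol, and none of the 6 kept its call with an estimated correlation. Interferon-stimulated genes had a mean log2 fold change of -0.09, with negative values in 18 of 21 members (camera adjusted p = 5.17e-06; adjusted p = 0.207 with an estimated correlation). MX1 measured 2.00 ± 0.524 and 1.33 ± 0.327 FPKM and OAS3, an antiviral synthetase, 2.44 ± 0.282 and 2.01 ± 0.175 (SD, n = 4 each). Endothelial identity genes had a mean of -0.06, negative in 23 of 28 (camera adjusted p = 0.000518; adjusted p = 0.444 with an estimated correlation). CLEC14A stood at 51.3 ± 5.55 and 45.1 ± 3.09 FPKM and CLDN5, a tight junction protein, at 2.03 ± 0.540 and 1.6 ± 0.258. In the pair of libraries described in the last paragraph the endothelial mean was 0.04 and in the other 6 it was -0.09. Vasoactive genes had a mean of -0.04, negative in 12 of 19 (camera adjusted p = 0.0168; adjusted p = 0.161 with an estimated correlation). The endothelin receptor EDNRB stood at 3.94 ± 0.322 and 3.43 ± 0.465 FPKM and the vasodilator peptide gene ADM at 16.6 ± 2.48 and 14.7 ± 1.2.

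The lipid and mesenchymal lists showed smaller shifts. Lipid efflux genes had a mean log2 fold change of -0.04, negative in 9 of 11 (camera adjusted p = 0.0267; adjusted p = 0.348 with an estimated correlation). The cholesterol exporter ABCA1 stood at 4.26 ± 0.264 and 3.85 ± 0.20 FPKM and CAV1, the caveolar coat protein, at 109.7 ± 7.67 and 102 ± 6.44 (SD, n = 4 each). Fatty acid synthesis genes had a mean of -0.04, negative in 15 of 18 (camera adjusted p = 0.0297; adjusted p = 0.427 with an estimated correlation). The desaturase SCD stood at 179 ± 5.90 and 171 ± 4.22 FPKM and the synthase FASN at 25.2 ± 5.38 and 23.0 ± 3.55. Mesenchymal genes had a mean of -0.04, negative in 17 of 25 (camera adjusted p = 0.0302; adjusted p = 0.444 with an estimated correlation). TWIST2 stood at 2.93 ± 0.440 and 2.43 ± 0.351 FPKM and the proteoglycan gene BGN at 7.31 ± 1.16 and 6.27 ± 0.938. By limma, 0 members of these 6 lists passed over all genes and 0 adjusted over the list alone. With 1 library left out, lipid efflux kept its call in 3 of 8 fits, fatty acid synthesis in 2, mesenchymal in 2, vasoactive in 4, endothelial identity in 6 and interferon response in 8. Endothelial identity lost its call without control replicate 1 (mean -0.012) or estradiol replicate 4 (-0.029), and its mean was -0.12 without control replicate 3. Vasoactive genes lost it without control replicate 1 or 3 or estradiol replicate 1 or 2, with means from -0.047 to -0.030. Lipid efflux lost it without any control library or estradiol replicate 4. Its mean was -0.082 without control replicate 3 and -0.023 without control replicate 4, and turned to 0.0081 without estradiol replicate 4. For fatty acid synthesis and mesenchymal genes the call was lost without any library but control replicate 3 and estradiol replicate 3. Their means were -0.012 and -0.015 without control replicate 1, -0.087 and -0.079 without control replicate 3, -0.027 and -0.024 without control replicate 4, and -0.0067 and -0.0018 without estradiol replicate 4. The interferon mean was -0.051 without control replicate 2 and -0.13 without estradiol replicate 1. It was -0.01 in the pair of control replicate 3 and estradiol replicate 4 and -0.11 in the other 6 libraries. The means in the pair and in the other 6 were 0.00358 and -0.05 for fatty acid synthesis, -0.00298 and -0.06 for vasoactive, -0.07 and -0.03 for lipid efflux, and -0.02 and -0.04 for mesenchymal genes. Without the pair, lipid efflux (camera adjusted p = 0.173) and mesenchymal genes (0.0532) lost their calls. Without estradiol replicate 2 as well, lipid efflux (0.190), mesenchymal (0.0515) and interferon genes (0.0515) lost theirs.

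**Figure D2:**
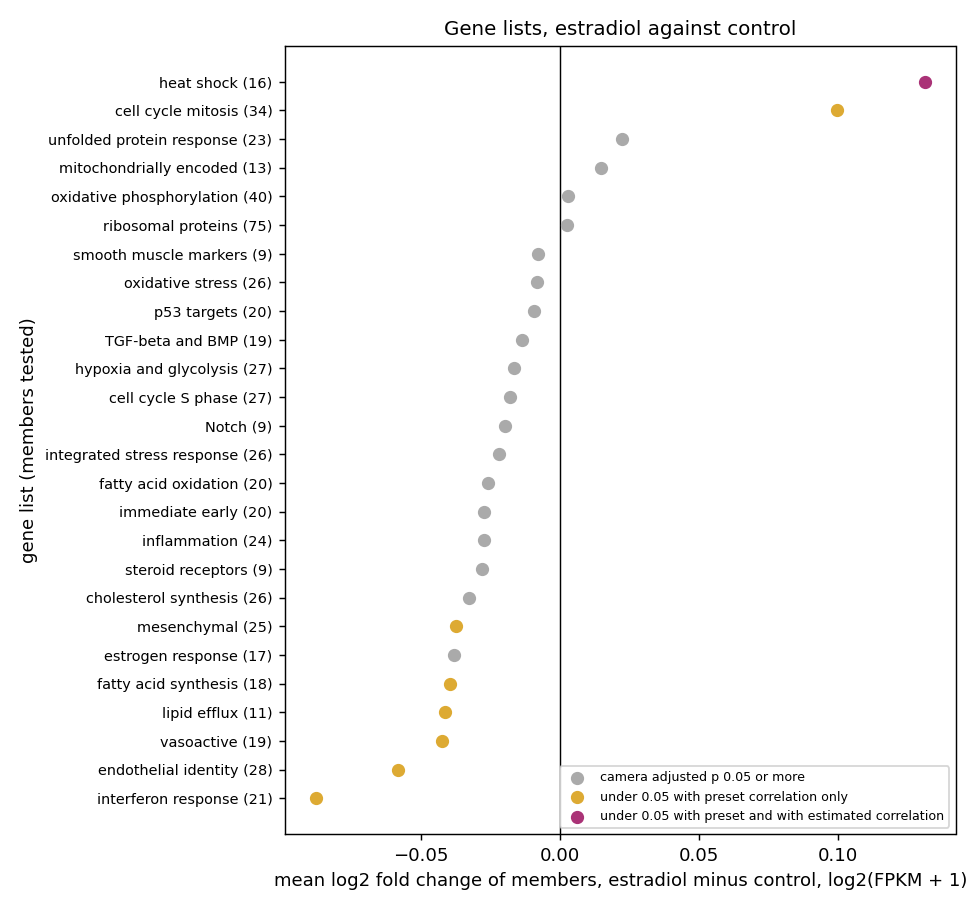
Mean log2 fold change of the members of each of the 26 tested lists, estradiol minus control on the log2(FPKM + 1) scale, with the number of members in brackets and colour showing the camera result. Heat shock genes stand at the right with 0.13 and are the only list past the threshold with both the preset and the estimated correlation.

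The other 18 lists did not pass camera. Among lipid and stress lists, mean log2 fold changes were -0.03 for cholesterol synthesis (adjusted p = 0.112; INSIG1 -0.10, HSD17B7 0.13), -0.03 for fatty acid oxidation (0.137; ANGPTL4 -0.28, SLC25A20 -0.10), 0.02 for the unfolded protein response (0.141; HSPA5 0.09, MANF 0.11), -0.02 for the integrated stress response (0.191; CHAC1 -0.10), -0.01 for oxidative stress (0.607; MT1X 0.26, AKR1B10 -0.11) and -0.01 for p53 targets (0.848; BTG2 0.06, TP53INP1 -0.09), with camera adjusted p and gene log2 fold changes in brackets. Inflammation stood at -0.03 (camera adjusted p = 0.0694; CCL2 -0.18, TNFAIP3 -0.11) and immediate early genes at -0.03 (0.191; NR4A2 -0.17, CCN1 0.07). Notch genes stood at -0.02 (0.345; HEY2 -0.09, JAG1 -0.08), TGF-beta and BMP genes at -0.01 (0.345; ID1 0.24, LTBP2 -0.10), smooth muscle markers at -0.01 (0.607; MYLK -0.08) and steroid receptors with their coregulators at -0.03 (0.248; NR3C2 -0.06, NCOA1 -0.05). Ribosomal protein genes stood at 0.00243 (0.805; RPL17 0.11, RPL24 0.10) and oxidative phosphorylation genes at 0.00301 (0.773; NDUFB2 0.11, UQCRFS1 -0.07). Hypoxia and glycolysis genes had a mean of -0.02 and a median of 0.000782 (0.336; MXI1 -0.15, ALDOA -0.19). Mitochondrially encoded genes had a mean of 0.01, a median of -0.03 and a negative direction by camera (0.483; ND6 0.37, ND1 -0.06).

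The composition of the libraries did not differ between the groups beyond their spread. Mitochondrially encoded genes took 7.79 ± 0.673% of summed FPKM in control and 7.67 ± 0.773% in estradiol libraries (SD, n = 4 each; exact permutation p = 0.80), ribosomal protein genes 9.95 ± 0.738% and 9.98 ± 0.786% (exact permutation p = 0.971), and the 10 most abundant genes 11.4 ± 0.354% and 11.3 ± 0.412% (exact permutation p = 0.543). The number of genes at 1 FPKM or more was 10675 ± 22.1 and 10733 ± 157 (exact permutation p = 0.686).

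The largest difference among the libraries did not follow the groups. The first principal component held 68.7% of the variance and set control replicate 3 and estradiol replicate 4 apart from the other 6 libraries. Across genes, which are not independent replicates, the deviation of a library from the median of all 8 had a rank correlation with GC content of -0.865 in control replicate 3 and -0.845 in estradiol replicate 4, against -0.339 to 0.650 in the other 6. The labels name no batch. Taken as a batch of a library per group, the pair gave a mean log2 fold change of 0.11 for heat shock and 0.13 for mitosis genes, and the other 6 libraries gave 0.14 and 0.09. In the other 6 alone, a set chosen after seeing the data, limma gave 0 genes and 416 at an unadjusted p under 0.05, and with a batch term for the pair it gave 0 and 351. Both counts were fewer than chance gives on average over the genes tested. Estradiol replicate 2 had a mean log2 deviation of 0.42 over antisense genes, against -0.13 to 0.05 in the other 7 libraries. Over genes with LOC symbols it was also 0.42, against -0.11 to 0.08 in the other 7.

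**Figure D3:**
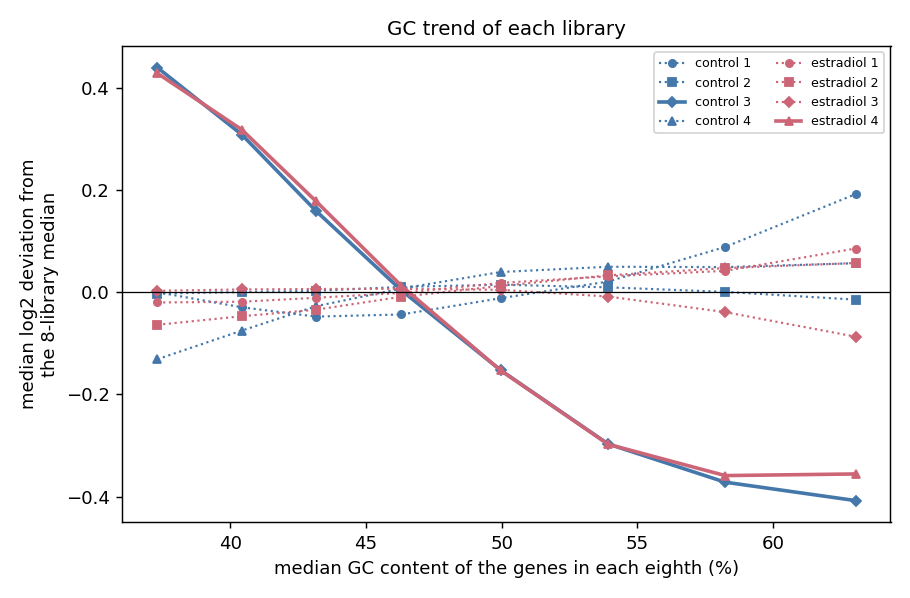
Median log2 deviation of genes from their median over the 8 libraries, for genes in eighths of GC content (x axis in percent), with a line per library. Control replicate 3 and estradiol replicate 4 fall from 0.44 and 0.43 in the lowest eighth to -0.41 and -0.36 in the highest, and the other 6 stay between -0.13 and 0.19.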

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

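The tests of GC content, gene length and depth for the pair of libraries, and the test of immediate early genes, were chosen only after the result was seen. Of 34 groups of 4 libraries examined for a value far from the other 3, 4 held such a value, and chance gives about 1 in 20. The lipid efflux score of control replicate 3 was 3.69 and that of estradiol replicate 4 was 3.63, each far below the rest of its group. The mesenchymal score of estradiol replicate 4 was 5.08, also far below its group. ESR1 stood at 0.0300 FPKM in estradiol replicate 2, far above its group. That was 19 recovered reads, against 10 in control replicate 3 and 0 to 2 in each of the rest.

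Control replicate 3 and estradiol replicate 4 stood apart from the other 6 libraries, the pair that holds 3 of those values. A GC trend is a large part of this but was not shown to be the whole cause. A fall of the first component's share of variance to under 50% of its value had been set as the mark of GC content as the cause. Removal of the trend by a spline took the share from 73.5% to 38.6%, which is 52.4% of its value (95% bootstrap interval over genes 50.5 to 55.4), and removal by medians of 20 bins left 52.8%. The mark was thus missed both ways, while the variance on that component fell to 20.4% of its size and the pair still had the highest weights. Gene length is argued against by its partial rank correlation given GC content, at most 0.0893 in size in the pair. Lower depth is not supported, since 1 of the other libraries held fewer reads than the deeper of the pair, although the other 5 held more. No biological explanation was tested, since the pair holds a library of each group, and an unnamed library batch stays open.

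Estradiol replicate 2 held more antisense transcripts, with 29 antisense genes more than 2-fold above the median of the libraries. The excess was not particular to antisense genes. In this library the mean log2 deviation was also 0.416 over genes with LOC symbols and 0.195 over divergent transcripts, but -0.034 over intergenic transcripts. The filter on mean FPKM included this library, so genes can have entered through a high value in it. Control replicate 3 held 8 such genes and the other 6 libraries 0 or 1. Loss of strand information in this library may contribute. For 102 antisense genes that overlap an exon on the other strand, the excess was compared with the log ratio of partner to own level. Their rank correlation was 0.616 (permutation p = 0.0001, the smallest its permutations can give). A low own level can raise both the excess and the ratio, so part of this correlation may be built in. The permutation does not keep that shared term and takes genes of 1 library as independent. Its p therefore does not measure loss of strand information. The same correlation reached 0.383 in another library, whose own values enter the ratio. Genomic DNA is argued against by olfactory receptor genes, whose depth-scaled reads were 0.838 times the highest of the other 7 libraries. An effect of estradiol is not tested by a pattern in 1 of its 4 libraries.

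Heat shock genes were higher with estradiol. With the GC trend removed, the camera adjusted p was 6.59e-17 and the mean log2 fold change still 0.13, which argues against GC content as the source of the difference, although the SD of the group scores rose from 0.0488 and 0.0342 to 0.0748 and 0.0615 and the adjusted p with an estimated correlation moved from 0.00805 to 0.0555. Without the pair that p was 0.0678. No library alone carried the mean, which ranged from 0.114 to 0.152 with 1 library left out. The highest camera adjusted p of these fits was 0.000262, with the preset correlation. The mitosis and interferon lists also passed all 8 such fits but not with an estimated correlation, so passing them is weak evidence. Fits with 1 library left out were not run with an estimated correlation. Handling stress at harvest was read from immediate early genes. Their mean log2 fold change of -0.027 is not beyond its spread, with an SD of the group scores of 0.184 and 0.107, 8 members higher and 12 lower, and means from -0.11 to 0.040 with 1 library left out. Handling stress therefore stays open, as do an effect of estradiol and differences in culture between the groups.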

How the results depend on the processing

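Alternatives named here as chosen after seeing the data are limma-voom, GC removal, the fits without the pair of libraries (control replicate 3 and estradiol replicate 4) or also without estradiol replicate 2, the batch term for the pair, and the exact permutation of list means. The count of genes past the threshold was 0 under each of the 22 other limma settings, with a 2-fold threshold and by exact permutation per gene. At an unadjusted p under 0.05 it was 26 with the settings of the report, 888 with array weights, 437 without the filter, 416 without the pair, 351 with a batch term, 249 with the GC trend removed, 4 with a filter at 5 FPKM and 15 to 183 with 1 library left out. The genes tested were 23471 without the filter, 7221 with a filter at 5 FPKM, 10526 with the GC trend removed and otherwise 10720. Only the count with array weights was above what chance gives on average over the genes tested. Those weights were 0.109 for control replicate 3, 0.110 for estradiol replicate 4 and 6.52 for control replicate 2.

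The labels do not say whether the replicate numbers pair the libraries. Deviations of same-numbered libraries from their group means correlated at 0.616, 0.0728, -0.478 and -0.737, and 1 of 4 control libraries correlated best with its own number. Control replicate 3 and estradiol replicate 4, which carry different numbers, weigh heavily in these deviations. The correlations therefore cannot decide whether the numbers pair the libraries. With the number as a block, 0 genes passed (11 at an unadjusted p under 0.05) and 6 lists.

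The number of lists past the threshold was 8, and 1 with an estimated correlation, 1 by directional fry, 0 by mixed fry, 0 by exact permutation of list means and 5 to 12 with 1 library left out. The mitosis list (0.0996) lost its call with an estimated correlation, by fry and by permutation. The heat shock list (0.131) lost it by mixed fry (adjusted p = 0.966) and by permutation (adjusted p = 0.743), where no lone list can pass. It also lost it where an estimated correlation was joined to another change, with an adjusted p of 0.0555 with the GC trend removed and 0.0678 without the pair. With 1 library left out heat shock ranged from 0.114 to 0.152. Lists lower with estradiol lost calls with these camera adjusted p. Lipid efflux lost it with no filter (0.0786), array weights (0.277), the replicate block (0.0598), without the pair (0.173) and without estradiol replicate 2 as well (0.190). Mesenchymal genes lost it with no filter (0.0786), array weights (0.192), without the pair (0.0532) and without estradiol replicate 2 as well (0.0515), where interferon response also lost it (0.0515). Fatty acid synthesis lost it with no filter (0.0745), array weights (0.0772) and the replicate block (0.0509).

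Lists that did not pass with the settings of the report turned direction by camera in places, the cause not tested. Some also passed with 1 library left out, ribosomal proteins in 5 of 8 fits (higher in 3 and lower in 2), mitochondrially encoded and estrogen response in 3 each, inflammation in 2, and immediate early, integrated stress response and oxidative phosphorylation in 1 each. The mitochondrially encoded calls went both ways, lower without control replicate 1 (camera adjusted p = 0.00126) and higher without estradiol replicate 1 (0.00695). Other settings also gave calls, with these camera adjusted p. Without the pair, ribosomal proteins (0.0228) and oxidative phosphorylation (0.0173) passed as higher, but not with an estimated correlation (0.719 and 0.477). Without estradiol replicate 2 as well, both passed as higher (0.000118 and 0.0249) and Notch as lower (0.0336). The rest passed as lower: cholesterol synthesis with the GC trend removed (0.0173), a batch term (0.0121) or a filter at 5 FPKM (0.0283), fatty acid oxidation with the GC trend removed (0.0429), array weights (0.0329) or no filter (0.0440), inflammation with no filter (0.0189), TGF-beta and BMP with a filter at 5 FPKM (0.0192), and estrogen response with rescaling to a common total (0.0335), median-of-ratios factors (0.0324), a filter at 5 FPKM (0.0235) or the GC trend removed (0.0429). With the GC trend removed and an estimated correlation, cholesterol synthesis (0.132), fatty acid oxidation (0.254) and estrogen response (0.254) did not pass. An estimated correlation was not run with the settings that called Notch, inflammation and TGF-beta and BMP. With the settings of the report it gave 0.757, 0.530 and 0.530 for them. The mean log2 fold changes of lists that turned direction follow. With a filter at 5 FPKM they were 0.026 for S phase and 0.0045 for smooth muscle. With array weights they were 0.015 for immediate early, 0.017 for p53 targets, -0.011 for ribosomal and 0.019 for smooth muscle. Without the filter they were 0.0030 for oxidative phosphorylation and -5.84e-06 for ribosomal. With the GC trend removed they were -0.00025 for oxidative phosphorylation and -0.0043 for smooth muscle. Without the pair they were 0.087 for mitochondrially encoded, -0.0060 for p53 targets and -0.00022 for smooth muscle, and mitochondrially encoded gave 0.0079 without estradiol replicate 2 as well.

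With 1 library left out, list means ranged from -0.093 to 0.016 for Notch, -0.028 to 0.0093 for TGF-beta and BMP, -0.089 to 0.0090 for estrogen response, -0.056 to 0.025 for hypoxia and glycolysis, -0.11 to 0.040 for immediate early, -0.088 to 0.035 for integrated stress response, -0.042 to 0.12 for mitochondrially encoded, -0.031 to 0.067 for oxidative phosphorylation, -0.036 to 0.025 for oxidative stress, -0.029 to 0.012 for p53 targets, -0.051 to 0.084 for ribosomal proteins, -0.059 to 0.051 for smooth muscle, -0.053 to -0.0039 for steroid receptors, and from -0.063 to 0.0066 for inflammation, -0.057 to 0.0041 for fatty acid oxidation and -0.042 to -0.0033 for S phase. The group difference ranged from -0.376 to 0.224 for the percent of summed FPKM in mitochondrially encoded genes, from -0.239 to 0.402 for the percent of summed FPKM in ribosomal protein genes, and from -16.8 to 99.8 for the number of genes at 1 FPKM or more.

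Log2 fold changes of genes with 1 library left out ranged from -0.0050 to 0.0096 for ESR1, -0.0015 to 0.0060 for ESR2, -0.052 to 0.047 for GPER1, -0.076 to 0.0076 for SNAI2, -0.0086 to 0.021 for COL1A1, -0.15 to 0.94 for ND6, -0.13 to 0.020 for ND1, -0.20 to 0.051 for TP53INP1, -0.15 to 0.051 for ACTA2, -0.055 to 0.026 for PECAM1, -0.16 to 0.051 for CDH5, -0.23 to 0.033 for NOS3, -0.30 to 0.060 for KLF2, -0.10 to 0.18 for TAGLN, -0.072 to 0.071 for FN1 and -0.090 to 0.0091 for VIM. FN1 was at 0.0065 without the pair, and TAGLN at -0.029 without estradiol replicate 2 as well. For receptors and other genes under the filter, the filter at 5 FPKM, quantile normalization, the fit without the trend and array weights were not run. None of these genes passed under any setting run.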

Other observations

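The exact permutation of list means was chosen only after the result was seen. Among the 35 ways of splitting the 8 libraries into groups of 4, the real split was compared with the others. With 0 genes past the threshold in the real split, 35 of 35 splits gave as many, as any split must, so this count says nothing about chance; the highest other gave 1. At an unadjusted p under 0.05 the real split gave 26 genes and 25 of the 35 splits gave as many; the highest other gave 4293, a split with control replicate 3 and estradiol replicate 4 on the same side, which points to a structure of the samples. Among the 20 splits that part these 2 libraries, as the real split does, 10 gave as many and the highest other gave 80, so chance is not excluded. The 15 other splits gave 234 or more. The real split gave 8 lists past the threshold, 3 of 35 splits gave as many and the highest other gave 9, so chance is not excluded for the number of lists.

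For single lists the shares of splits are not adjusted over lists. The real split alone reached its camera p, 1 of 35, for heat shock (4.97e-12, the smallest p of another split 7.26e-07), cell cycle mitosis (6.91e-15, other 8.56e-10), vasoactive (0.00322, other 0.00683), lipid efflux (0.00617, other 0.0288) and fatty acid synthesis (0.00799, other 0.0563). The exact permutation p of the list mean was 0.0286 for heat shock, 0.171 for mitosis, 0.0571 for vasoactive, 0.457 for lipid efflux and 0.486 for fatty acid synthesis, and 0.743 or more after adjustment over 26 lists. For heat shock both are the smallest values the 8 libraries can give, so chance is excluded for that list only if it is taken alone and all 35 splits are taken as alike, and not for it as 1 of 26 lists; with the GC trend removed its groups overlap. Chance is not excluded for the other 4. The 20 splits that part control replicate 3 and estradiol replicate 4 are too few for a share under 0.05. Chance was not excluded for endothelial identity (7.97e-05, 2 of 35, other 4.96e-05), mesenchymal (0.00931, 2 of 35, other 0.00411) and interferon response (5.96e-07, 4 of 35, other 1.08e-15). Other splits of the same libraries thus gave camera p-values with the preset correlation far below 0.05.

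ND6, the mitochondrial gene on the opposite strand from the other mitochondrial messenger RNAs, stood at 171 FPKM in control replicate 3 and 201 in estradiol replicate 2, against 29.5 to 55.1 in the other 6 libraries.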
